A study of Mus musculus with 18 samples.

How the data were processed

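Gene expression was measured by RNA sequencing in 18 libraries of primary mouse microglia, in 6 groups of 3. The groups were Trem2+/+ and R47H/+ cells, each without and with 0N4R tau fibrils, and R47H/+ cells with MK-2206, without and with tau. Per the labels, reads were aligned and counted by the authors with STAR and featureCounts on GRCm38 (mm10), DESeq2 was also named, and no versions or settings were given. The deposited values are raw counts per gene, whole numbers with no normalization. The other deposited columns used here are gene coordinates and gene length in base pairs, which the authors gave beside each gene. Of 54495 gene identifiers also in GENCODE M21, 53585 (98.3%) had the same start and end. The table held 54532 genes, 27 symbols turned into dates were restored, and 103 rows had a repeated symbol. Library totals lay between 16288531 and 20686299 counts, and between 17321 and 18626 genes had a count. Chi-square per gene between replicates lay between 3.75 and 335, so the spread exceeded counting error.

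Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept by filterByExpr (13267 tested), libraries were scaled by TMM, and 1 quasi-likelihood model with a term per group was fitted over all 18 libraries, with 12 residual degrees of freedom. Each of 7 pairwise comparisons and 2 interactions was tested by the two-sided quasi-likelihood F-test with Benjamini-Hochberg adjustment over all genes tested, at a threshold of 0.05. CPM values are means with the SD of 3 libraries and log2 CPM used a prior count of 2. An exact permutation of 3 against 3 cannot give a p under 0.1, so none is given.

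The comparisons, the 25 gene lists with 636 entries, the rule for named genes and the first set of alternatives were fixed before the data were examined. Lists were tested by camera with a preset correlation of 0.01, adjusted over the 25 lists, and again with an estimated correlation; 1 list symbol was absent from the table. The lists were inflammatory cytokines and chemokines, NF-kB feedback and target genes, type I interferon-stimulated genes, antigen presentation, homeostatic microglia, disease-associated microglia, cholesterol synthesis and uptake, fatty acid synthesis, cholesterol efflux, FOXO target genes, glycolysis and hypoxia response, cell cycle, lysosome and TFEB target genes, ATF4 and amino acid response, NRF2 oxidative stress response, complement, Fc and scavenger receptors, alternative activation, markers of astrocytes, the oligodendrocyte lineage, neurons, fibroblasts and vessels, and border macrophages, monocytes and granulocytes, mitochondrially encoded genes, Trem2 neighbours on chromosome 17 and sex-linked genes.

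Named genes were Trem2, up to 8 higher and 8 lower genes with the largest change per pairwise comparison (4 and 4 per interaction) among those called with a mean log2 CPM of at least 1 and, for pairs, group ranges that did not overlap, up to 4 members per list with the smallest p, and Tnf, Il1b, Cxcl10, Apoe, P2ry12, Irs2 and Mki67. Some genes within this rule are not reported here. Clone names, Rik symbols and pseudogenes were left out. Alternatives were RLE scaling, no count filter, DESeq2, a fit of the compared groups alone, a replicate block, fry, an estimated correlation, and each library left out. Leaving out both length-shifted libraries and a lowess offset for gene length (span 0.3) were chosen after seeing the data.

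The model was tested on simulated data for MK-2206 against R47H/+ cells without tau only (12806 genes). It recovered 13.6% of genes changed 1.5-fold, 43.3% at 2-fold and 93.8% at 4-fold, and 3 unchanged genes were called, 2.63% of calls. The shifted list was called and 0 others were. Genes were drawn independently and no simulated library was length-shifted. The simulation therefore cannot show how often lists of correlated genes are called wrongly in these data.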

Results

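RNA sequencing counts were analysed for primary mouse microglia, the resident macrophages of the brain, grown from newborn pups that were either Trem2+/+ or carried the R47H form of TREM2 on 1 allele (R47H/+). TREM2 is a lipid-sensing surface receptor of microglia. Cells of both genotypes were left without tau or received 0N4R tau fibrils at 1 ug per ml. All cells had a 6 h pre-treatment, with 0.01% DMSO as vehicle in the groups without MK-2206. Further R47H/+ cells were pre-treated with 1 uM MK-2206, an inhibitor of the kinase Akt, for which no DMSO share is given. This gave 6 groups of 3 libraries, and the design asks for the baseline state of R47H/+ cells, their response to tau and the effect of MK-2206 on both. The 18 libraries held between 16288531 and 20686299 counts each, and 13267 genes passed the count filter. Nothing in the labels says that the replicates were separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical.

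In Trem2+/+ replicate 3 and in R47H/+ with tau replicate 2, long genes were low and short genes high relative to the other replicates of the group, with slopes of -1.27 and -0.60 log2 CPM per 10-fold gene length, against -0.10 to 0.19 in the other 16 libraries. Mitochondrially encoded genes took 0.863% and 0.661% of the counts of these libraries. Each count of changed genes is therefore also given without both libraries, an alternative chosen after seeing the data. Of the astrocyte markers, Gfap lay at 1.09 CPM or less in the mean of every group, Aldoc between 3.69 and 15.4, Fabp7 between 7.01 and 31.3 and Aldh1l1 between 27.2 and 85.8 CPM, and Mbp, a myelin gene, lay between 57.7 and 121.8 CPM.

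**Figure D1:**
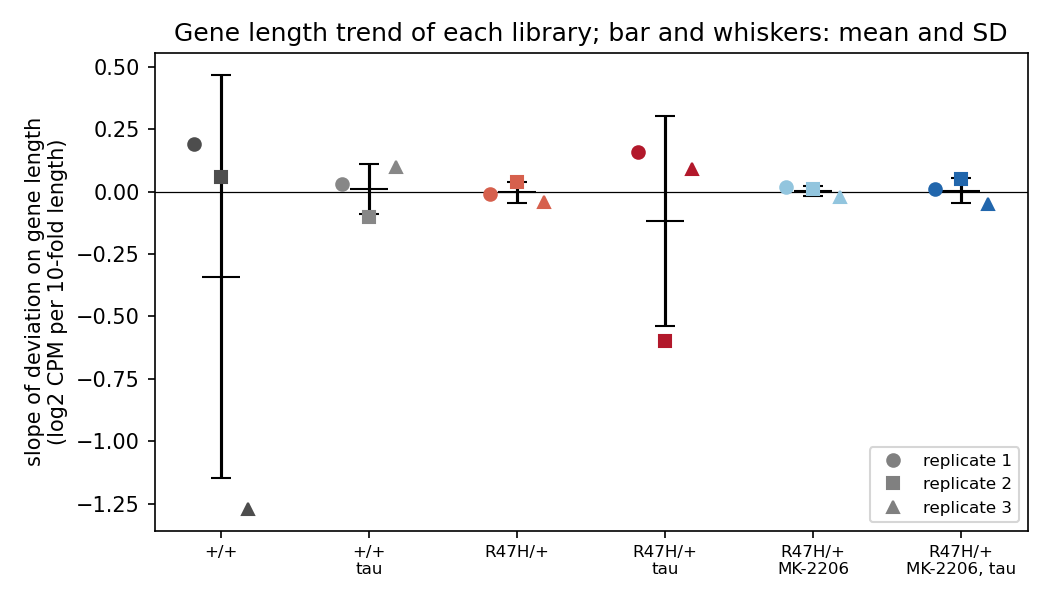
Slope of each library's deviation from its group median on gene length, in log2 CPM per 10-fold length, for the 18 libraries in 6 groups; points are libraries and bars with whiskers are the mean and SD of 3. Trem2+/+ replicate 3 lies at -1.27 and R47H/+ with tau replicate 2 at -0.60, and the other 16 lie between -0.10 and 0.19.

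Trem2 itself (ENSMUSG00000023992, chromosome 17, 48346401 to 48354147, GRCm38) was lower in every R47H/+ library without tau than in every Trem2+/+ library without tau. It measured 945.4, 935.0 and 1894 CPM in the Trem2+/+ libraries and 451.2, 453.8 and 489.1 CPM in the R47H/+ libraries. With tau the values were 468.5, 480.7 and 375.3 CPM in Trem2+/+ and 128.2, 243.0 and 154.7 CPM in R47H/+ cells. R47H/+ cells with MK-2206 held 502.7, 551.4 and 505.2 CPM without tau, and 183.4, 153.8 and 169.9 CPM with tau. Trem2 fell by 1.44 on the log2 scale from Trem2+/+ to R47H/+ cells (SE 0.251, adjusted p = 0.000821, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Without Trem2+/+ replicate 3 the log2 change was -1.04. A fit of these 6 libraries alone, which still held that replicate, gave -1.46 with an adjusted p of 0.0667, which ended the call. Leaving out both length-shifted libraries gave -1.02 and kept the call (adjusted p = 1.9e-08, same test). Per the genotype labels a mouse Trem2 allele is replaced in R47H/+ cells, so the edit itself may lower these counts. How much of the fall comes from the edit was not tested.

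**Figure D2:**
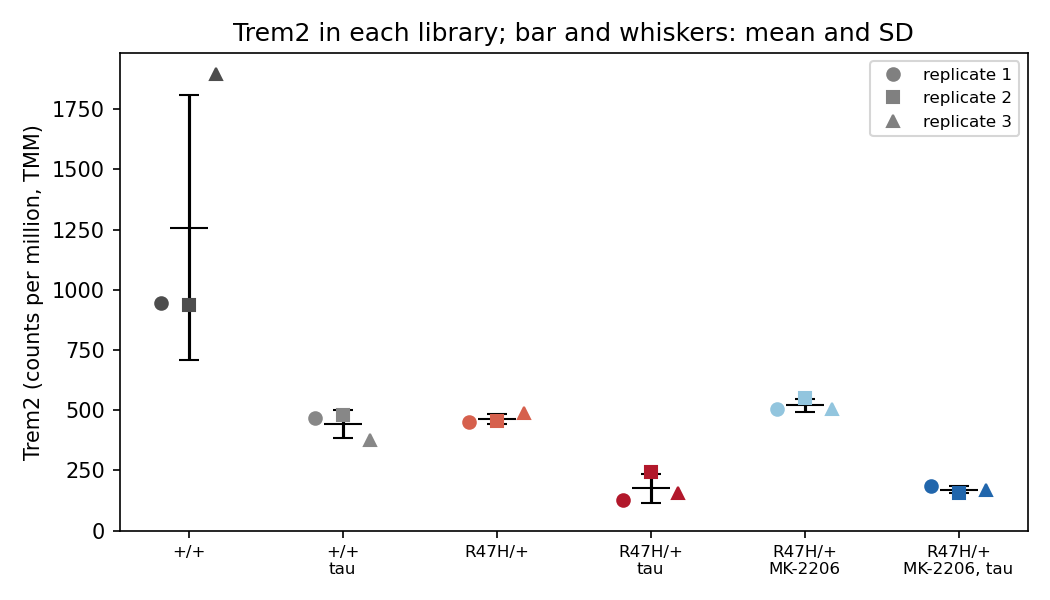
Trem2 in CPM for each of the 18 libraries; points are libraries and bars with whiskers are the mean and SD of 3 per group. The 3 R47H/+ libraries without tau lie between 451.2 and 489.1, below the 3 Trem2+/+ libraries at 935.0 to 1894, and each tau group lies below its group without tau in the mean.

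Without tau, R47H/+ microglia carried much higher levels of interferon-stimulated genes than Trem2+/+ microglia. Gbp4, an interferon-induced GTPase, measured 27.7 ± 0.908 CPM against 0.924 ± 0.431 CPM (SD, n = 3 each), a log2 change of 4.85 (SE 0.226), and Ms4a4c rose by 4.52 (SE 0.277). The T cell and monocyte chemokines Ccl2, Ccl7 and Ccl5 rose by 2.32, 2.99 and 2.88, and Cxcl10 rose by 1.48, while Tnf fell by 1.09. Ccl5 was at 3.60 without Trem2+/+ replicate 3, and at 3.61 without both length-shifted libraries (edgeR quasi-likelihood, adjusted p = 5.19e-11). A fit of these 6 libraries alone ended the calls of Ccl5, Cxcl10 and Tnf (adjusted p = 0.0635, 0.143 and 0.0672). F13a1, Chil3 and Fn1, genes of macrophage matrix and alternative activation, fell by 2.77, 2.46 and 2.36, and Egr2, a transcription factor, fell by 2.31.

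Of the 51 type I interferon-stimulated genes, 50 rose and 0 fell, and 50 rose when adjusted over the list alone, with a median log2 change of 2.07. Ifi44, Oasl1, Irf7, the interferon-induced master regulator of interferon genes, and Ifit2 rose by 4.19, 3.75, 3.44 and 3.17 (camera adjusted p = 2.4e-62, and adjusted p = 0.000302 with an estimated correlation). Antigen presentation had 20 of 28 members higher (21 adjusted over the list alone), among them H2-Q6, whose reads may be shared with the near-identical H2-Q7, at 4.06 and the peptide transporter Tap1 at 1.99 (adjusted p = 4.74e-14, and adjusted p = 0.0527 with an estimated correlation). The ATF4 and amino acid response list had 13 of 25 members higher and 2 lower (16 and 2 adjusted over the list alone), with Slc1a4 and Trib3 up by 2.35 and 2.29 (adjusted p = 3.39e-07). In the homeostatic microglia list 10 of 27 rose and 2 fell (11 and 2 adjusted over the list alone), with the purinergic receptors P2ry13 and P2ry12 up by 1.55 and 1.43 (adjusted p = 0.00297).

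Several metabolic lists were lower in R47H/+ cells. The NRF2 oxidative stress response had 16 of 22 members lower and 0 higher (18 adjusted over the list alone), with Gclm, an enzyme of glutathione synthesis, down by a log2 change of -1.15 (camera adjusted p = 6.94e-12). Of the 26 genes of glycolysis and hypoxia response, 16 fell and 0 rose (17 and 2 adjusted over the list alone), with the glucose transporter Slc2a1 at -0.91 and Pkm at -0.83 (adjusted p = 2.86e-07). Of the 25 genes of cholesterol synthesis and uptake, 13 fell and 0 rose (16 and 1 adjusted over the list alone), with Cyp51 at -1.19 (adjusted p = 1.76e-07). Alternative activation had 7 of 16 members lower and 3 higher (8 and 3 adjusted over the list alone), with Arg1 at -1.44 (adjusted p = 0.0118).

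Weaker calls concerned inflammatory cytokines and chemokines (11 of 27 higher, 2 lower; 14 and 4 adjusted over the list alone; camera adjusted p = 0.00962, and adjusted p = 0.407 with an estimated correlation and 0.165 without Trem2+/+ replicate 1) and lysosome and TFEB target genes (9 of 38 higher, 3 lower; 14 and 4 adjusted over the list alone; adjusted p = 0.0228, and adjusted p = 0.125 with an estimated correlation and 0.0534 and 0.0716 without Trem2+/+ replicates 1 and 2). Astrocyte markers were called lower (adjusted p = 0.0118, and adjusted p = 0.22 with an estimated correlation), with 4 of 12 lower and 1 higher (6 and 1 adjusted over the list alone) and Aldoc at 5.75 against 15.4 CPM. Mitochondrially encoded genes had 4 of 12 lower (5 adjusted over the list alone; adjusted p = 0.0105, and adjusted p = 0.28 with an estimated correlation). The lists not called by camera of limma were NF-kB feedback and target genes (adjusted p = 0.199), disease-associated microglia (adjusted p = 0.0548), fatty acid synthesis (adjusted p = 0.177), cholesterol efflux (adjusted p = 0.716), FOXO target genes (adjusted p = 0.382), cell cycle (adjusted p = 0.201), complement, Fc and scavenger receptors (adjusted p = 0.382), oligodendrocyte lineage (adjusted p = 0.0782), neuron (adjusted p = 0.199), fibroblast and vascular (adjusted p = 0.205), border macrophage, monocyte and granulocyte markers (adjusted p = 0.0683), Trem2 neighbours on chromosome 17 (adjusted p = 0.504) and sex-linked genes (adjusted p = 0.329), all adjusted by Benjamini-Hochberg over the 25 lists tested by camera. Without both length-shifted libraries fatty acid synthesis was called lower here (median -0.27, camera adjusted p = 0.00125). Over all comparisons the median, mean and test of a list differed in sign in 25 of 225 tests with all libraries, and 0 of these were called.

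In all, 1997 genes changed between R47H/+ and Trem2+/+ cells without tau, 1091 higher and 906 lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below the threshold of 0.05). Without both length-shifted libraries 3907 genes changed, 1904 of them shared, and leaving out 1 library gave between 1295 genes (without R47H/+ replicate 2) and 2975 (without Trem2+/+ replicate 1), with 1321 without R47H/+ replicate 1, and a fit of the 6 libraries alone called 474. Gbp10 and Apol9a had 1 and 4 counts in all 3 Trem2+/+ libraries together, so no fitted fold is given; Gbp10 had 110 counts in R47H/+, a ratio of 113 with a 95% counting interval of 19.8 to 4500. Both genes have near-identical copies, so the assignment of their reads is uncertain.

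Tau fibrils raised interferon-stimulated and inflammatory genes in Trem2+/+ microglia. The chemokine Ccl5 rose from 10.97 ± 8.31 to 1277 ± 101 CPM (SD, n = 3), a log2 change of 6.88 (SE 0.480). Slc13a3 rose by 7.26 (SE 0.338) from 25 counts, and the nitric oxide synthase Nos2 rose from 0.114 CPM, on 7 counts, to 11.4 CPM. Ccl5 was at 7.58 without Trem2+/+ replicate 3. Cxcl10 rose by 4.09. Tnf rose by 0.53, a call lost in a fit of these 6 libraries alone (adjusted p = 0.223). The call was also lost without replicates 1 or 2 of Trem2+/+ (adjusted p = 0.0862 and 0.0777) or of Trem2+/+ with tau (adjusted p = 0.0522 and 0.082). Il1b, at -0.78 (adjusted p = 0.0846, edgeR quasi-likelihood with Benjamini-Hochberg adjustment), was not called. It was called without Trem2+/+ replicate 1 (-1.05). Slco2b1, Mamdc2 and Hpgd fell by 5.53, 4.11 and 3.78, and Trem2 fell by 1.51. The value for Slco2b1 rests on 20 counts in all libraries with tau together. Apoe fell by 1.16 (adjusted p = 0.121 in a fit of these 6 libraries alone) and Irs2, an adaptor of insulin receptor signalling, fell by 1.84. P2ry12, a homeostatic microglial receptor, rose by 1.75.

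All 51 interferon-stimulated genes rose, also adjusted over the list alone, with a median log2 change of 2.60 and Oasl1 at 5.24 (camera adjusted p = 2.08e-52, and adjusted p = 0.000711 with an estimated correlation). Of the 27 cytokines and chemokines, 19 rose and 1 fell (20 and 2 adjusted over the list alone), with Cxcl9 at 5.68 (6.37 without Trem2+/+ replicate 2) and Il1rn, the interleukin 1 receptor antagonist, at 1.97 (adjusted p = 1.6e-09, and adjusted p = 0.148 with an estimated correlation). NF-kB feedback and target genes had 22 of 35 higher and 1 lower (25 and 1 adjusted over the list alone), with Cd40, Acod1 and Vcam1 at 2.74, 4.20 and 3.63 (adjusted p = 5.02e-08, and adjusted p = 0.148 with an estimated correlation). Antigen presentation had 21 of 28 members higher (24 adjusted over the list alone; adjusted p = 3.41e-14, and adjusted p = 0.103 with an estimated correlation). Of 25 genes of cholesterol synthesis and uptake 19 fell and 0 rose (20 adjusted over the list alone), with Cyp51 at -1.86 and Sqle at -1.68 (adjusted p = 3.19e-11, and adjusted p = 0.00158 with an estimated correlation). Disease-associated microglia genes had 20 of 34 lower and 4 higher (23 and 4 adjusted over the list alone), with Cd9 at -2.18 and Cst7, a cysteine protease inhibitor, at 3.10 (adjusted p = 2.79e-05, and adjusted p = 0.135 with an estimated correlation). The ATF4 list had 16 of 25 higher and 1 lower, and 16 and 1 adjusted over the list alone, with Chac1 at 3.16 (adjusted p = 9.17e-08, and adjusted p = 0.0242 with an estimated correlation). Mitochondrially encoded genes had 7 of 12 lower (8 adjusted over the list alone; adjusted p = 0.000354, and adjusted p = 0.167 with an estimated correlation).

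Tau changed 3519 genes in Trem2+/+ cells, 1913 higher and 1606 lower (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). With both length-shifted libraries left out 5589 genes changed, 3300 of them shared, and a fit of these 6 libraries alone called 1311. Without both length-shifted libraries fatty acid synthesis was also called lower (median -0.41, camera adjusted p = 0.00918).

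In R47H/+ microglia tau raised cytokine genes from a different starting level. Tnf rose from 12.7 ± 1.64 to 73.8 ± 7.46 CPM (SD, n = 3), a log2 change of 2.53 (SE 0.172), Ccl2 rose by 4.08, Cxcl10 by 4.65 and Il1rn by 3.47. Slc13a3 and Serpina3g rose by 7.81 and 6.14 (8.44 and 6.84 without R47H/+ replicate 3), and Traf1, an NF-kB target, by 5.65. Without tau Slc13a3 and Serpina3g had 14 and 22 counts in all R47H/+ libraries together. Slco2b1, Hpgd and Mamdc2 fell by 6.59, 5.21 and 4.78, and Trem2 fell by 1.41. The value for Slco2b1 rests on 10 counts in all libraries with tau together. Il1b was at 0.87 (adjusted p = 0.0533) and Apoe at -0.42 (adjusted p = 0.291), neither called by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. With both length-shifted libraries left out both were called, at 0.68 and -0.70 (adjusted p = 0.0186 and 1.22e-05).

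Of the 27 cytokines and chemokines 22 rose and 0 fell (23 adjusted over the list alone), with a median log2 change of 3.11 (camera adjusted p = 3.31e-18, and adjusted p = 0.035 with an estimated correlation). NF-kB genes had 26 of 35 higher and 1 lower (26 and 2 adjusted over the list alone), with Cd40 at 4.05 and Vcam1 at 4.59 (adjusted p = 2.09e-14, and adjusted p = 0.0352 with an estimated correlation). Interferon-stimulated genes had 41 of 51 higher (45 adjusted over the list alone), with a median of 1.21 and Cmpk2 at 2.66 (adjusted p = 4.25e-24). Cholesterol synthesis and uptake had 22 of 25 lower and 0 higher, adjusted over the list alone also 22, with Cyp51 at -2.46 and Sqle at -2.45 (adjusted p = 5.74e-15). Of 42 cell cycle genes 15 rose (17 adjusted over the list alone), with the spindle gene Tpx2 at 2.65 and the replication helicase gene Mcm5 at 1.11 (adjusted p = 2.87e-06). Homeostatic genes had 10 of 27 lower and 4 higher (11 and 4 adjusted over the list alone), with Gpr34 at -3.32, Gpr183 at -4.05 and P2ry13 at 1.35 (adjusted p = 0.0174). The ATF4 list had 16 of 25 higher and 1 lower (19 and 1 adjusted over the list alone; adjusted p = 9.79e-08), and lysosome genes 12 of 38 lower and 2 higher (14 and 4 adjusted over the list alone; adjusted p = 0.00356).

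Calls lost with an estimated correlation here were antigen presentation (18 of 28 higher, 1 lower; 20 and 1 adjusted over the list alone; adjusted p = 0.106 with an estimated correlation), FOXO target genes (15 of 36 lower, 5 higher; 16 and 6 adjusted over the list alone; adjusted p = 0.105 with an estimated correlation), glycolysis and hypoxia response (12 of 26 higher, 3 lower, and 12 and 3 adjusted over the list alone; adjusted p = 0.106 with an estimated correlation) and mitochondrially encoded genes (6 of 12 lower, and 6 adjusted over the list alone; adjusted p = 0.149 with an estimated correlation). Oligodendrocyte lineage markers were called lower (adjusted p = 0.0384, and adjusted p = 0.0782 with an estimated correlation), with Mbp at -0.79. That call was also lost without R47H/+ replicate 3, R47H/+ with tau replicate 1 or both length-shifted libraries (adjusted p = 0.0591, 0.0583 and 0.0603). Fibroblast and vascular markers were called higher (adjusted p = 0.0414, and adjusted p = 0.105 with an estimated correlation and 0.132 without R47H/+ replicate 3, 0.118 and 0.113 without R47H/+ with tau replicates 1 and 3), with the receptor gene Kdr at 78.9 against 28.0 CPM. Tau changed 3667 genes in R47H/+ cells, 1991 higher and 1676 lower (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), and 5773 without both length-shifted libraries, 3556 of them shared. Without both, disease-associated microglia and fatty acid synthesis were also called lower (camera adjusted p = 0.00853 and 0.0486). Complement, Fc and scavenger receptors were then called higher (camera adjusted p = 0.032).

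The tau responses of both genotypes shared 1974 genes that changed in the same direction, against 490 for independent lists of these sizes, and 54 genes changed in opposite directions. With both length-shifted libraries left out 3884 were shared. No library was shared between these comparisons. Across genes, which are not independent replicates, the fold changes correlated at 0.64.

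With tau present, R47H/+ microglia had higher levels of chemokine and cytokine genes than Trem2+/+ microglia. Ccl2 measured 295.6 ± 48.4 against 56.0 ± 5.78 CPM (SD, n = 3), a log2 change of 2.40 (SE 0.238), and Ccl7, Ccl12 and Nos2 rose by 2.91, 2.49 and 2.54. Ch25h, which makes the oxysterol 25-hydroxycholesterol, rose by 2.47, Il1rn by 2.19, Cxcl10 by 2.03 and Tnf by 0.91. Il1b rose by 1.16, a call lost without replicates 1 or 2 of Trem2+/+ with tau (adjusted p = 0.143 and 0.113) or of R47H/+ with tau (adjusted p = 0.0509 and 0.132). The matrix protease gene Mmp9 fell by 3.08 (SE 0.205) from its level of 177.1 ± 18.1 CPM in Trem2+/+ cells, and F13a1, Chil3 and Igfbp4 fell by 2.84, 2.18 and 1.98. Trem2 was lower by a log2 change of -1.33.

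Of 27 cytokines and chemokines 19 were higher and 0 lower (22 adjusted over the list alone; median 1.25; camera adjusted p = 2.02e-16, and adjusted p = 0.0411 with an estimated correlation). Interferon-stimulated genes had 27 of 51 higher (34 adjusted over the list alone), with Rsad2 at 1.21 and Cmpk2 at 1.14 (adjusted p = 5.85e-19). Cell cycle genes had 10 of 42 higher (15 adjusted over the list alone), with Tpx2 and Ccna2 at 1.71 and 1.58 (adjusted p = 4.13e-09), while Mki67 was at 0.03 and not called. Cholesterol synthesis and uptake had 19 of 25 lower and 1 higher (22 and 1 adjusted over the list alone), with Sqle at -1.82 and Cyp51 at -1.79 (adjusted p = 1.16e-16). The ATF4 list had 10 of 25 higher (13 adjusted over the list alone; adjusted p = 1.33e-06), with the stress factor Ddit3 at 1.53. Oligodendrocyte lineage markers were called lower (adjusted p = 0.0072) with 2 of 16 lower, adjusted over the list alone also 2.

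Among calls lost with an estimated correlation, NF-kB genes had 10 of 35 higher (15 and 1 lower adjusted over the list alone; adjusted p = 0.172 with an estimated correlation), antigen presentation 8 of 28 higher (11 adjusted over the list alone; adjusted p = 0.163 with an estimated correlation), FOXO target genes 5 of 36 lower and 2 higher (11 and 3 adjusted over the list alone; adjusted p = 0.13 with an estimated correlation), and the NRF2 list 7 of 22 lower and 1 higher (9 and 1 adjusted over the list alone; adjusted p = 0.133 with an estimated correlation). Fatty acid synthesis had 3 of 18 lower (4 adjusted over the list alone; adjusted p = 0.341 with an estimated correlation). Fibroblast and vascular markers were called higher, and border macrophage markers and mitochondrially encoded genes lower, with adjusted p = 0.133, 0.131 and 0.398 with an estimated correlation. The comparison changed 1260 genes, 697 higher and 563 lower (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). With both length-shifted libraries left out 3141 genes changed, 1235 of them shared, while leaving out 1 library gave 629 (without Trem2+/+ with tau replicate 1), 769 (its replicate 2), 780 (without R47H/+ with tau replicate 2) and up to 1041.

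**Figure D3:**
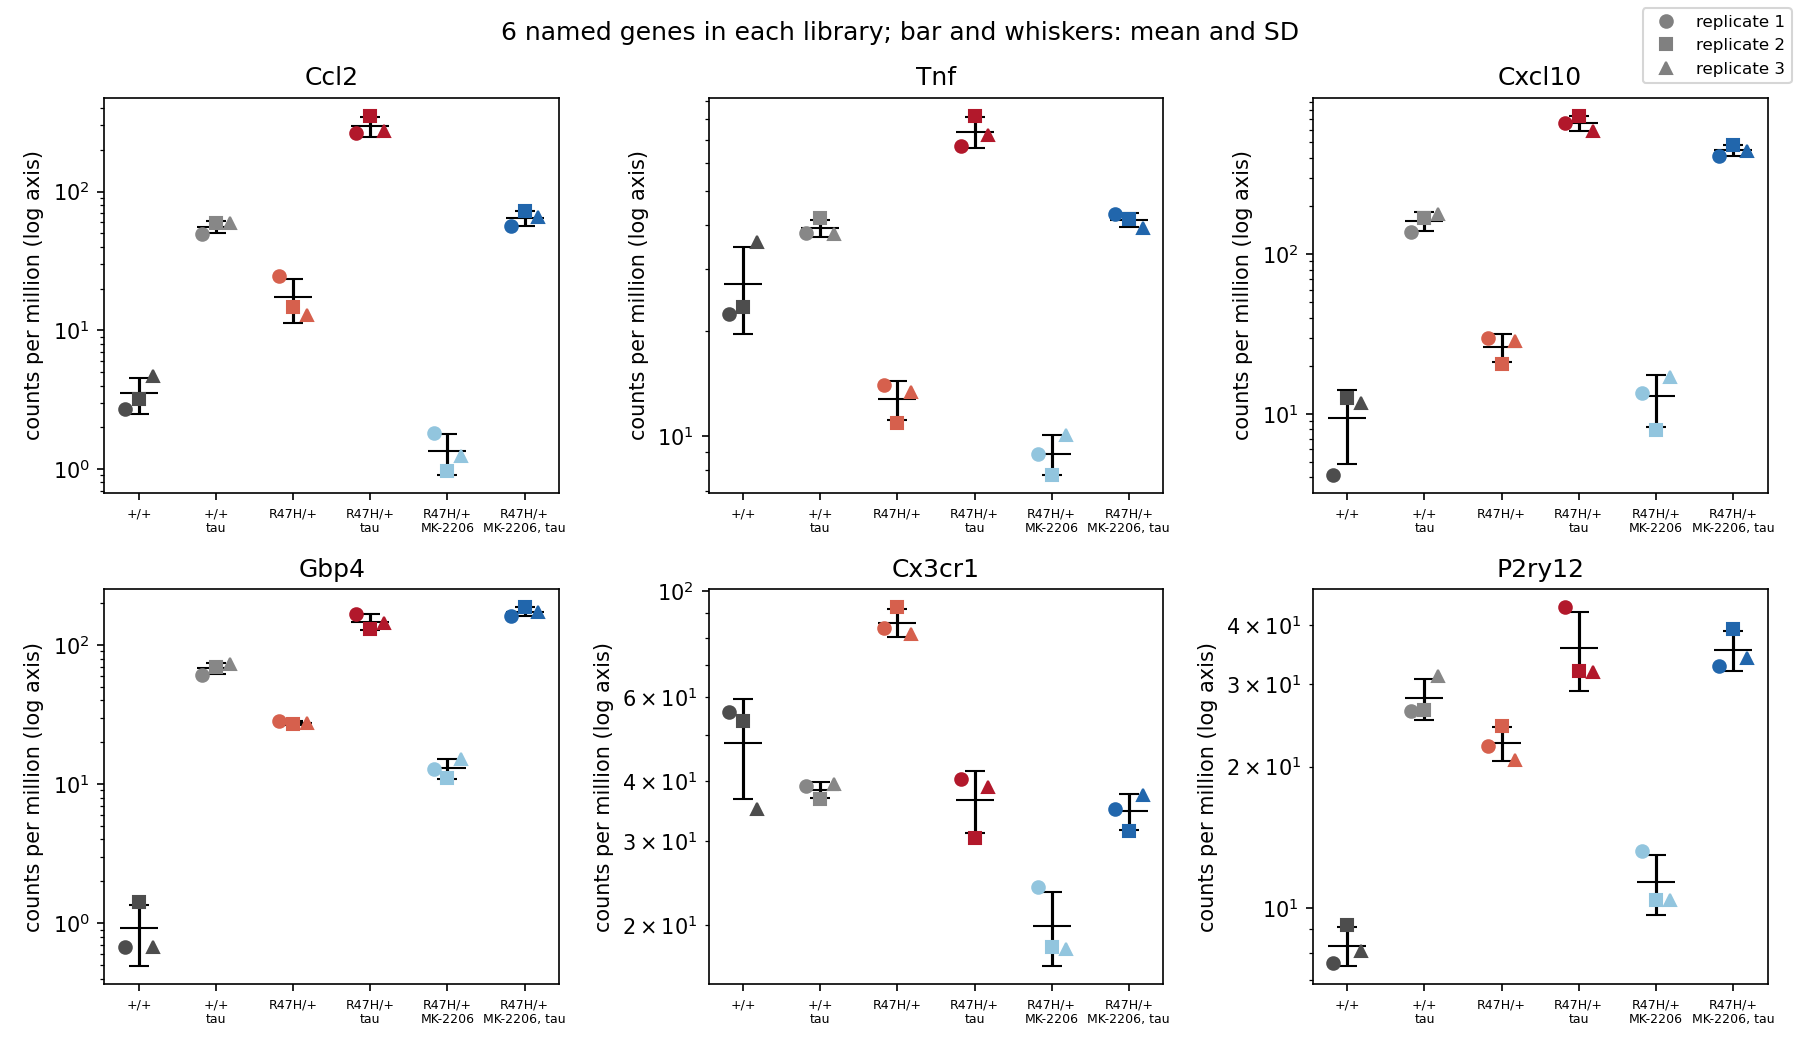
CPM, on a log axis, of Ccl2, Tnf, Cxcl10, Gbp4, Cx3cr1 and P2ry12 in each of the 18 libraries; points are libraries and bars with whiskers are the mean and SD of 3 per group. Ccl2 lies near 295.6 CPM in R47H/+ cells with tau, against 56.0 in Trem2+/+ cells with tau and 64.7 in R47H/+ cells with tau and MK-2206.

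Without tau, MK-2206 lowered the chemokine genes Ccl2 and Ccl7 and genes of the homeostatic and cell cycle lists in R47H/+ microglia, while cytokines and chemokines as a list had 4 of 27 lower (adjusted p = 0.352 with an estimated correlation). Ccl2 fell by 3.69 (SE 0.288), from 17.4 ± 6.20 to 1.35 ± 0.436 CPM (SD, n = 3), and Ccl7 fell by 4.45. Cx3cr1, the fractalkine receptor of microglia, fell by 2.11 (SE 0.174) and P2ry12 by 0.98, and Ccnd1, a cyclin of the start of the cell cycle, fell by 2.15. Angptl4, Gadd45a and Mamdc2 rose by 2.10, 1.84 and 1.89, and Arg2 rose by 1.77. Trem2 was at 0.16 and Cxcl10 at -1.04 (adjusted p = 0.981 and 0.118, edgeR quasi-likelihood with Benjamini-Hochberg adjustment), neither called. Leaving out both length-shifted libraries called Cxcl10 (-1.03, adjusted p = 0.00519).

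Interferon-stimulated genes had 10 of 51 lower and 0 higher (27 lower adjusted over the list alone), with a median log2 change of -0.41 and Oasl1 at -0.88 (camera adjusted p = 4.03e-21, and adjusted p = 0.012 with an estimated correlation). Homeostatic genes had 9 of 27 lower (11 and 1 higher adjusted over the list alone; adjusted p = 1.12e-08), and cell cycle genes 4 of 42 lower (7 adjusted over the list alone), with Mcm5 at -0.94, not called without R47H/+ with MK-2206 replicate 2 (camera adjusted p = 3.62e-12). The ATF4 list had 8 of 25 lower and 1 higher (9 and 2 adjusted over the list alone), with Slc1a4 at -1.72 and Asns, the asparagine synthetase, at -1.07 (adjusted p = 1.86e-08). FOXO target genes, which Akt is known to restrain, had 7 of 36 higher and 2 lower (13 and 2 adjusted over the list alone), with Fbxo32 at 1.26 (adjusted p = 0.000286, and adjusted p = 0.0681 with an estimated correlation). Of the cytokine and chemokine list 7 fell when adjusted over the list alone (adjusted p = 0.352 with an estimated correlation), and the NRF2 list 2 of 22 higher (3 adjusted over the list alone; adjusted p = 0.061 with an estimated correlation). Antigen presentation and cholesterol synthesis were called lower as lists with 0 members called (0 and 1 adjusted over the list alone; adjusted p = 0.364 and 0.0583 with an estimated correlation). Border macrophage markers were called lower with Ccr2 at -1.42 and 3 of 12 lower (4 adjusted over the list alone; adjusted p = 0.14 with an estimated correlation), and the Trem2 neighbours were called higher with 0 members called, also 0 adjusted over the list alone (adjusted p = 0.103 with an estimated correlation). MK-2206 changed 338 genes, 158 higher and 180 lower (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Without both length-shifted libraries, neither of which belongs to these groups, 1878 genes changed, including all 338. Disease-associated microglia genes were then called higher (camera adjusted p = 0.0126). Border macrophage markers and the Trem2 neighbours then lost the call (camera adjusted p = 0.115 and 0.0627). Leaving out any 1 of the 6 libraries compared gave 138 (without R47H/+ with MK-2206 replicate 2) to 198 genes, and a fit of these 6 alone called 2236.

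With tau, MK-2206 lowered the chemokine genes Ccl2 and Ccl7 and cell cycle genes and raised FOXO targets in R47H/+ cells, while cytokines and chemokines as a list had 6 of 27 lower (adjusted p = 0.389 with an estimated correlation). Ccl2 fell by 2.19 (SE 0.236), from 295.6 ± 48.4 to 64.7 ± 7.84 CPM (SD, n = 3), Ccl7 by 2.78, Ch25h by 1.88 and Tnf by 0.84. Tnf was not called without R47H/+ with tau replicate 2 or R47H/+ with tau and MK-2206 replicate 3 (adjusted p = 0.0503 and 0.0588). The chemokine receptor gene Cxcr4 rose by 1.75 (SE 0.097), Dkk2, an inhibitor of Wnt signalling, by 2.44 and Mamdc2 by 2.71. Uhrf1, which maintains DNA methylation, fell by 1.84. Cxcl10 at -0.56, Il1b at 0.27, Irs2 at 1.05 and Trem2 at -0.05 were not called. Leaving out both length-shifted libraries called Irs2 (0.80, adjusted p = 0.00142).

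Cell cycle genes had 10 of 42 lower and 0 higher (23 adjusted over the list alone), with Mcm5 at -1.43 and Uhrf1 at -1.84 (camera adjusted p = 3.6e-17, and adjusted p = 8.65e-05 with an estimated correlation). FOXO target genes had 7 of 36 higher and 0 lower (13 adjusted over the list alone), with the cell cycle inhibitor Cdkn1b at 0.54 (adjusted p = 8.47e-09, and adjusted p = 0.0155 with an estimated correlation). The ATF4 list had 5 of 25 lower (8 adjusted over the list alone), with Psat1 at -1.03 (adjusted p = 5.31e-07, and adjusted p = 0.0304 with an estimated correlation). Cytokines and chemokines had 6 of 27 lower (10 adjusted over the list alone; adjusted p = 2.81e-06, and adjusted p = 0.389 with an estimated correlation), glycolysis genes 2 of 26 lower and 1 higher (8 and 1 adjusted over the list alone; adjusted p = 0.273 with an estimated correlation), and cholesterol synthesis 1 of 25 higher, adjusted over the list alone also 1 (adjusted p = 0.0876 with an estimated correlation). None of the 51 interferon-stimulated genes was called, adjusted over the list alone also 0, and the list was not called (camera adjusted p = 0.568). With tau, MK-2206 changed 403 genes, 217 higher and 186 lower (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Without both length-shifted libraries 1620 genes changed, 398 of them shared. Leaving out any 1 of the 6 libraries gave 150 (without R47H/+ with tau and MK-2206 replicate 1) to 245 genes, and a fit of these 6 alone called 220.

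The MK-2206 effects with and without tau shared 92 genes changed in the same direction, against 5.11 for independent lists, and 1 gene changed in opposite directions. Leaving out 1 library gave 47 (without R47H/+ replicate 1) to 69 shared genes, and leaving out both length-shifted libraries 558. Of the genes that differed by genotype with tau, 170 moved the opposite way with MK-2206 and tau, against 19.0 for independent lists, with 81 that were higher in R47H/+ and 89 that were lower. Both comparisons use the R47H/+ libraries with tau. The covariance of the fold changes was -0.133, against -0.045 in 20 simulated sets, and their correlation was -0.51, against a simulated -0.50. In each set all groups, also the shared one, were redrawn without change from the mean levels of the shared group. The real shared libraries, among them the length-shifted one, were thus absent. The simulation therefore cannot show how much of the covariance the real shared libraries give. The 170 genes became 74 (without R47H/+ with tau and MK-2206 replicate 1) to 144 when 1 library was left out, and 724 without both length-shifted libraries. Without tau 198 genes moved oppositely, against 25.6, with a covariance of -0.156 against a simulated -0.046 and a correlation of -0.46 against -0.50. This count was 80 (without R47H/+ replicate 1) to 200 when 1 library was left out, and 986 without both length-shifted libraries. Part of either excess may come from the shared libraries. Between the genotype effect with tau and the MK-2206 effect without tau, which share no library, 126 genes moved oppositely, against 16.2, and 21 moved the same way. The 126 became 52 (without R47H/+ replicate 1) to 115 with 1 library left out, and 754 without both length-shifted ones. Between the genotype effect without tau and the MK-2206 effect with tau, which also share none, the order was different, with 52 moving oppositely, against 30.1, and 117 the same way. The 52 became 20 (without R47H/+ with tau and MK-2206 replicate 1) to 71 with 1 library left out, and 304 without both length-shifted ones.

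In R47H/+ cells treated with MK-2206, tau raised cytokines, NF-kB targets and interferon-stimulated genes. Ccl2 rose by 5.58 (SE 0.299), from 1.35 ± 0.436 to 64.7 ± 7.84 CPM (SD, n = 3), Tnf by 2.21 and Cxcl10 by 5.12. Slco2b1 fell by 6.37, to 9 counts in all libraries with tau together, Angptl4 by 4.38, Irs2 by 2.23 and Trem2 by 1.62. Mki67, a marker of dividing cells, rose by 1.42.

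Cytokines and chemokines had 22 of 27 higher, adjusted over the list alone also 22, with a median log2 change of 2.44 (camera adjusted p = 1.45e-16, and adjusted p = 0.0388 with an estimated correlation). NF-kB genes had 28 of 35 higher and 1 lower, and 28 and 1 adjusted over the list alone (adjusted p = 7.28e-16). Interferon-stimulated genes had 47 of 51 higher (49 adjusted over the list alone), with Gbp2 at 3.66 (adjusted p = 1.44e-33), and cholesterol synthesis 17 of 25 lower (19 adjusted over the list alone), with Sqle at -1.98 (adjusted p = 1.49e-09). Cell cycle genes had 12 of 42 higher and 1 lower, and 12 and 1 adjusted over the list alone, with Tpx2 at 2.66 (adjusted p = 0.00245). The ATF4 list had 16 of 25 higher and 1 lower, and 16 and 1 adjusted over the list alone (adjusted p = 1.59e-06), and lysosome genes 12 of 38 lower and 2 higher (15 and 3 adjusted over the list alone; adjusted p = 0.00256). Antigen presentation had 20 of 28 higher (24 adjusted over the list alone; adjusted p = 0.0908 with an estimated correlation), disease-associated microglia genes 15 of 34 lower and 5 higher (19 and 6 adjusted over the list alone; adjusted p = 0.233 with an estimated correlation), and mitochondrially encoded genes 4 of 12 lower, also 4 adjusted over the list alone (adjusted p = 0.26 with an estimated correlation). This comparison changed 3393 genes, 1892 higher and 1501 lower (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), and 6475 without both length-shifted libraries, 3390 of them shared. A fit of these 6 libraries alone called 6225.

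**Figure D4:**
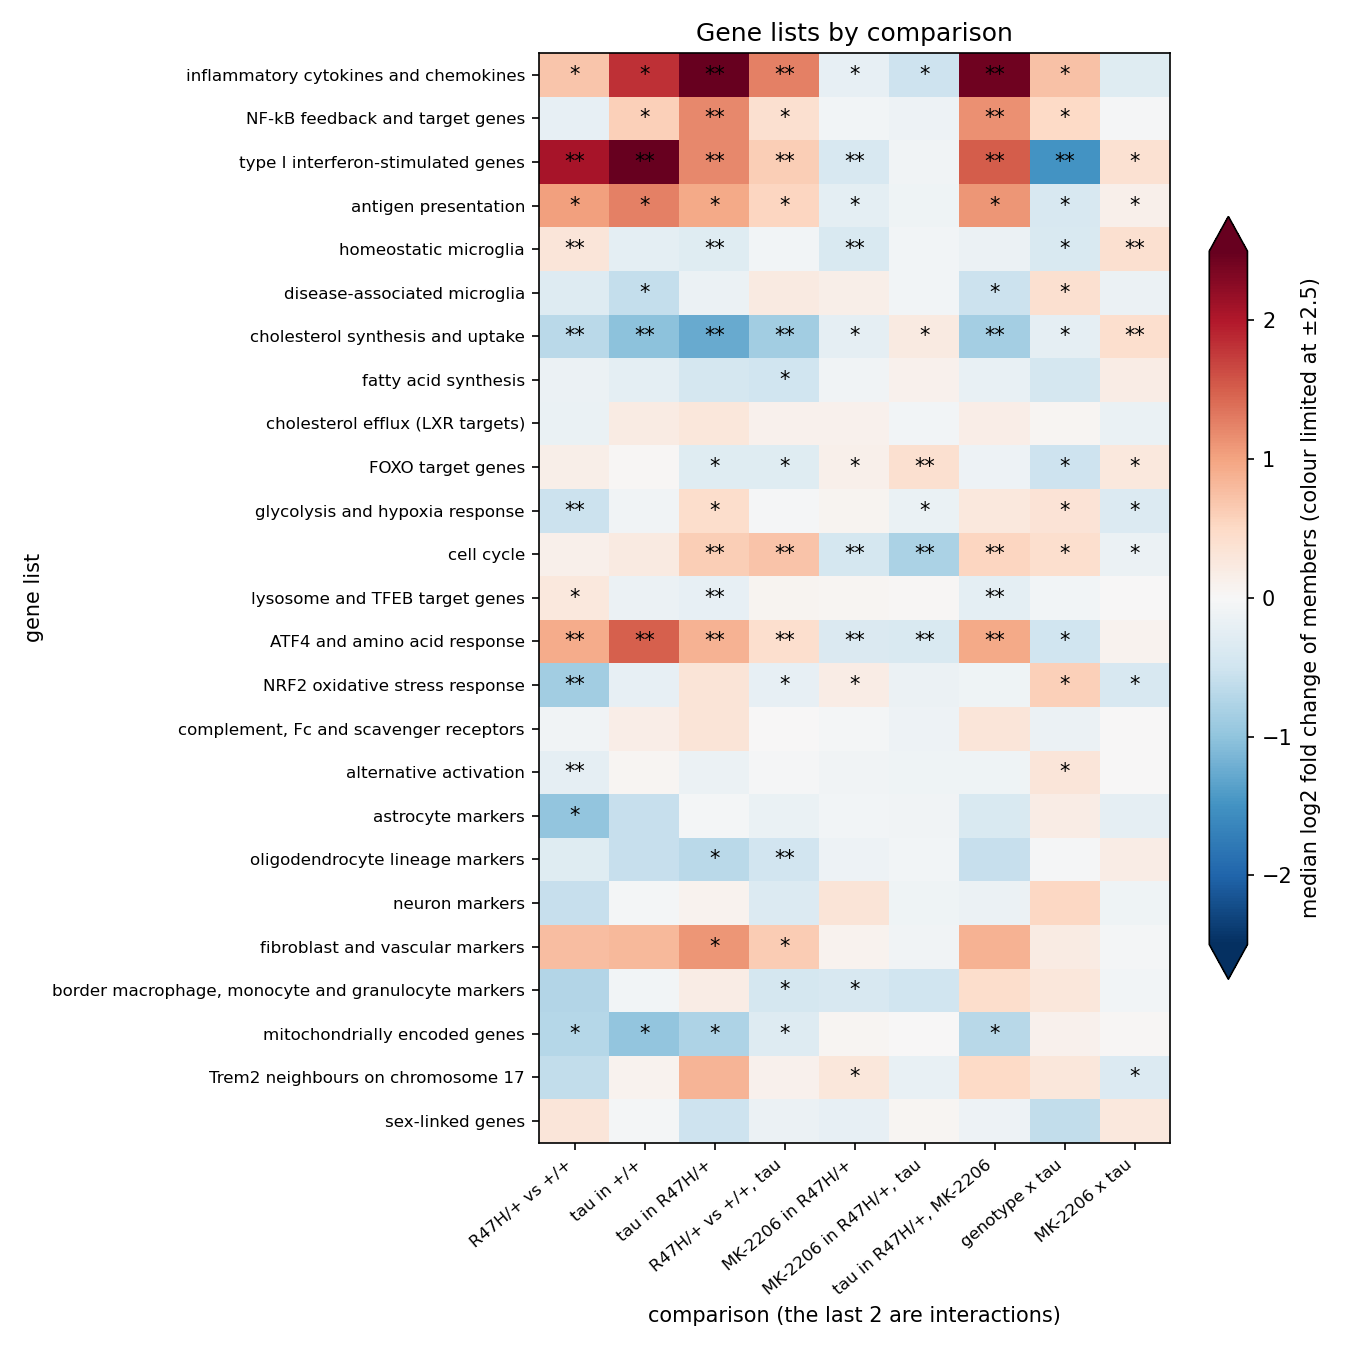
Median log2 fold change of each of the 25 gene lists (vertical axis) in the 9 comparisons (horizontal axis, the last 2 being interactions), with colours limited at plus and minus 2.5. A single asterisk marks a list called by camera with the preset correlation and a double asterisk one called also with an estimated correlation; interferon-stimulated genes lie at 2.07 for genotype without tau and at -1.50 for the interaction of genotype and tau.

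The tau response itself differed between genotypes for 713 genes, 272 with a more positive and 441 with a more negative change in R47H/+ cells (edgeR quasi-likelihood interaction test with Benjamini-Hochberg adjustment). The neutrophil chemokine Cxcl2, the adenosine receptor gene Adora2a, the phosphatase gene Dusp5 and the transcription factor gene Maff had the largest positive differences with all libraries, of 2.82, 2.79, 2.74 and 2.57 on the log2 scale. In Trem2+/+ cells Dusp5 and Maff went with tau from 6.57 and 7.05 to 2.56 and 2.27 CPM. In R47H/+ cells they went from 3.32 and 2.86 to 8.69 and 5.475 CPM. Cxcl2 went from 8.51 CPM (14.7 in replicate 3) to 4.83 CPM in Trem2+/+ and from 2.31 to 9.40 CPM in R47H/+ cells. Adora2a went from 1.54 to 4.81 CPM and from 0.436 to 9.64 CPM. Without Trem2+/+ replicate 3 Cxcl2 was at 2.22, below Adora2a, Dusp5 and Maff at 2.65, 2.59 and 2.60. Gbp4 had a negative difference of -3.74 (SE 0.281). Its level without tau was 27.7 CPM in R47H/+ and 0.924 CPM in Trem2+/+ cells. Of 51 interferon-stimulated genes 44 had a more negative change in R47H/+ cells and 0 a more positive one (47 adjusted over the list alone). The median of this list was -1.50 (camera adjusted p = 3.78e-44, and adjusted p = 0.00161 with an estimated correlation). Il1rn, the NF-kB inhibitor gene Nfkbie and Slc2a1 had more positive changes in R47H/+ cells, by 1.49, 1.73 and 1.09. Of the 13 lists called, the interferon list alone held with an estimated correlation. The length-shifted libraries both enter this contrast with the same sign, so their deviations, which correlated at 0.74 across genes, add up in it. Without both length-shifted libraries 1610 genes differed, 684 of them shared, and the median of the cytokine list went from 0.73 to 0.01. The calls of disease-associated microglia (from 0.40 to 0.09) and alternative activation (from 0.31 to -0.06) ended without them (adjusted p = 0.0959 for both). Trem2 was not called in the interaction (0.10, adjusted p = 0.861), and without both libraries it was called at -0.63 (adjusted p = 0.00326). Leaving out 1 library gave 471 (without R47H/+ replicate 2) to 1537 genes (without Trem2+/+ replicate 1), and a fit of the 12 libraries alone called 360.

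The tau response of R47H/+ cells differed with MK-2206 for 50 genes, 24 with a more positive and 26 with a more negative change (edgeR quasi-likelihood interaction test with Benjamini-Hochberg adjustment). The cytokine receptor gene Lifr, Cx3cr1, Tnfsf8 and Ccr2 had positive differences of 2.24, 2.03, 1.78 and 1.61, and Rims3, Angptl4, Htr2b and Syn1 negative ones of -2.27, -2.10, -1.81 and -1.72. Lifr and Cx3cr1 stayed called without any 1 of the 12 libraries. The others lost the call without R47H/+ replicate 2 (adjusted p = 0.0759 for Tnfsf8, Ccr2, Rims3 and Htr2b, 0.0834 for Angptl4 and 0.0825 for Syn1) and without some of the other libraries. Homeostatic microglia genes (median 0.40, adjusted p = 8.02e-07 by camera) and cholesterol synthesis genes (median 0.42, adjusted p = 2.33e-08) had more positive changes with MK-2206, and both held with an estimated correlation (adjusted p = 0.00165 and 0.00541). In the homeostatic list 1 of 27 members was called higher and 1 lower (7 and 1 adjusted over the list alone), and in the cholesterol list 0 of 25 (2 higher adjusted over the list alone). The other 7 of the 9 lists called lost the call with an estimated correlation. Leaving out both length-shifted libraries gave 667 genes, including all 50. Leaving out any 1 of the 12 libraries compared gave 9 (without R47H/+ replicate 2) to 43 genes (without R47H/+ with tau replicate 1), and a fit of these 12 alone called 187.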

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

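All tests of explanations and of other splits of the samples were chosen after the results were seen; the interaction tests themselves were planned.

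The tau response differed between genotypes, by the test of the interaction, for 713 genes. The largest differences were for Cxcl2 (2.82), Adora2a (2.79), Dusp5 (2.74), Maff (2.57), Gbp10 (-4.93), Apol9a (-4.14), Gbp11 (-3.78) and Gbp4 (-3.74). The fitted values of Gbp10, Apol9a and Gbp11 rest on 1, 4 and 8 counts in Trem2+/+ cells, and are no bound. Without Trem2+/+ replicate 3 Cxcl2 was at 2.22, below Adora2a, Dusp5 and Maff at 2.65, 2.59 and 2.60. Lists whose response differed had medians of 0.73 for inflammatory cytokines and chemokines, 0.49 for NF-kB targets, -1.50 for interferon-stimulated genes, -0.40 for antigen presentation, -0.39 for homeostatic microglia, 0.40 for disease-associated microglia, -0.23 for cholesterol synthesis and uptake, -0.52 for FOXO targets, 0.34 for glycolysis, 0.42 for cell cycle, -0.50 for the ATF4 list, 0.59 for the NRF2 list and 0.31 for alternative activation. Of these 13, the interferon list alone held with an estimated correlation (adjusted p = 0.00161), and the other 12 lost the call. The length-shifted libraries both enter this interaction with the same sign, so their shared deviations add up in these medians. When both length-shifted libraries were left out the median went to 0.09 for disease-associated microglia and to -0.06 for alternative activation (adjusted p = 0.0959 for both), which ended these calls, and to 0.01 for cytokines and chemokines. In that fit the median of antigen presentation went to -0.80 and that of FOXO targets to -0.28, and both stayed called by camera. Of 100 splits, 6 gave as many genes (713, highest other 2318) and 11 as many lists (13, highest other 16). The split with 2318 genes exchanged the genotypes in 1 of the tau conditions, so its contrast was the sum of the genotype effects of both conditions. The splits thus hold the genotype effect and do not show what chance alone gives, and chance was neither excluded nor shown to account for the result.

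The tau response of R47H/+ cells differed with MK-2206 for 50 genes. The largest differences were for Lifr (2.24), Cx3cr1 (2.03), Tnfsf8 (1.78), Ccr2 (1.61), Rims3 (-2.27), Angptl4 (-2.10), Htr2b (-1.81) and Syn1 (-1.72), of which Lifr and Cx3cr1 alone stayed called without R47H/+ replicate 2. List medians were 0.38 for interferon-stimulated genes, 0.12 for antigen presentation, 0.40 for homeostatic microglia, 0.42 for cholesterol synthesis and uptake, 0.26 for FOXO targets, -0.34 for glycolysis, -0.15 for cell cycle, -0.41 for the NRF2 list and -0.35 for Trem2 neighbours. Of these 9, the homeostatic (adjusted p = 0.00165) and cholesterol lists (adjusted p = 0.00541) held with an estimated correlation, and the other 7 lost the call. With both length-shifted libraries left out, the cell cycle list, at -0.13 (adjusted p = 0.088), and the Trem2 neighbours, at -0.16 (adjusted p = 0.0511), were not called. Of 100 splits, 2 gave as many genes (50, highest other 727) and 20 as many lists (9, highest other 11). The split with 727 genes exchanged the treatments in 1 of the tau conditions, so its contrast was the sum of the MK-2206 effects of both. These splits therefore hold the MK-2206 effect, and leave chance neither excluded nor shown to account for the result.

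For the pairwise comparisons 3 against 3 libraries make 10 splits, too few for a share under 0.05. The real split gave 1997, 3519, 3667, 1260, 338, 403 and 3393 genes, each as the 1 split with as many, and the highest other split gave 0. Each other split mixes libraries of both groups, so a real difference becomes spread within the groups. A count of 0 was therefore likely in advance and does not show what chance alone gives. For lists the real and highest other values were 12 and 8 for R47H/+ against Trem2+/+ without tau, 8 and 7 for tau in Trem2+/+, 14 and 13 for tau in R47H/+, 14 and 10 for genotype with tau, 11 and 11 for MK-2206 without tau (2 splits), 6 and 8 for MK-2206 with tau (3 splits) and 10 and 12 for tau with MK-2206 (2 splits).

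Trem2+/+ replicate 3 and R47H/+ with tau replicate 2 stood apart from their groups. Their deviations correlated with gene length across genes, at -0.40 in the weaker library, so a length trend may be part of the cause. It was not the whole cause, since their deviations still correlated at 0.68 after the trend was removed, against 0.74 before. Low depth was argued against by totals of 17.4 M or more, and a wrong label or swap within the series by the genes that part the own group from each other group: the libraries lay nearer their own at 70.6% of them or more, while 12 other libraries, left out in turn, lay nearer a group not their own at 28.1% at most. A first bound of 90% was given up because these other libraries missed it too (71.9%), and the correlation with the own group, higher by only 0.0046, did not decide. A sample from outside the series stays open. So does a technical cause shared by both libraries, which an offset for the given gene lengths need not remove. No other technical and no biological explanation was tested.

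Interferon-stimulated genes were higher in R47H/+ than in Trem2+/+ cells without tau. Without both length-shifted libraries the median was 2.03, which argues against the odd Trem2+/+ library. A stimulation like that of tau, moving all tau-raised genes in proportion, was weighed by the genotype change divided by the tau change in the MK-2206 arm. Its median was 1.35 for 47 interferon-stimulated genes and -0.11 for 28 NF-kB genes (3 higher, 8 lower in R47H/+). It was 0.34 for 22 cytokines and chemokines (11 higher, among them Ccl2 and Ccl7, and 2 lower). Differences were 1.02 or more, with a permutation p of 1e-05, the smallest that 100000 resamples can give. Genes are not independent. Interferon-stimulated genes were already raised in that arm before tau (list medians 2.07 for genotype, -0.41 for MK-2206). This may lower their divisor and raise their ratio, so these differences and the p decide nothing. All 47 interferon-stimulated genes were higher in R47H/+, against 15 of 22 cytokines and chemokines and 10 of 28 NF-kB genes. These directions ignore the divisor's size and argue against all tau-raised genes moving in proportion. A stimulus acting on interferon-stimulated genes and some chemokines, a difference between cultures or litters, of which the labels name none, and the genotype itself stay open.

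MK-2206 moved genes against the genotype difference with tau. The R47H/+ libraries with tau that both comparisons share were argued against as the whole cause, since comparisons without a shared library held 7.80 times as many genes in opposite directions as independent lists. The other pair without a shared library went the other way, with 117 genes in the same and 52 in opposite directions, although without tau, where a group is shared, 198 genes moved oppositely. Whether the inhibitor reverses the genotype difference was not tested.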

How the results depend on the processing

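Leaving out both length-shifted libraries and the gene length offset were chosen after seeing the data; the others were planned. RLE scaling kept every gene count, list count and overlap within 1.5 times. Where values moved the cause was not tested. Leaving out libraries or fitting the compared groups alone uses fewer samples, and no count filter tests more genes. MK-2206 without tau, which holds neither length-shifted library, rose from 338 genes to 1878 without both and 2236 in its groups alone. Tau with MK-2206, likewise, rose from 3393 to 6475 and 6225. These rises argue against fewer samples as their cause, although leaving out 1 compared library lowered both. Both settings take those libraries out of the spread shared by all groups. Replicate chi-square per gene reached 335 in Trem2+/+ and 97.8 in R47H/+ with tau, against 17.4 at most in other groups.

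Without both length-shifted libraries the counts were 3907 for R47H/+ against Trem2+/+ without tau, 5589 for tau in Trem2+/+, 5773 for tau in R47H/+, 3141 for genotype with tau, 1878 and 1620 for MK-2206 without and with tau, 6475 for tau with MK-2206, and 1610 and 667 for the interactions of tau with genotype and with MK-2206. The shared tau response was 3884, the opposite overlaps were 724 with tau, 986 without tau, 754 for genotype with tau and MK-2206 without and 304 for the reverse, and the shared MK-2206 effect was 558. Trem2 turned to -0.63 in the interaction of genotype and tau, and stayed called for genotype without tau (-1.02, edgeR quasi-likelihood, adjusted p = 1.9e-08).

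DESeq2 gave 550 and 698 genes for MK-2206 without and with tau, 1154 and 207 for the interactions, and overlaps of 292, 304, 220, 93 and 155 in the same order. The length offset gave 568, 686, 1071 and 135 genes and overlaps of 306, 320, 230, 95 and 166. No count filter gave 236 genes for MK-2206 with tau and overlaps of 108 (both with tau), 33 (genotype without and MK-2206 with tau) and 60 (MK-2206). The compared groups alone gave 474 genes for genotype without tau, 1311 for tau in Trem2+/+, 2236 and 220 for MK-2206 without and with tau, 6225 for tau with MK-2206 and 360 and 187 for the interactions, and Trem2 for genotype without tau was -1.46 (adjusted p = 0.0667).

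An estimated correlation left 7, 3, 8, 6, 4 and 3 lists for the first 6 pairwise comparisons and 1 and 2 for the interactions. By fry, which does not compare a list with other genes, 19 lists were called for genotype without tau, 16 for tau in Trem2+/+ and 16 for tau with MK-2206; the Trem2 neighbours, with a median of -0.61, were called up by fry for genotype without tau.

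The replicate numbers did not pair the libraries: of 45 pairs with the same number in different groups 4 correlated above 0.1, in a range of -0.63 to 0.49, and 5 libraries correlated best with their own number. With a replicate block 249 genes changed with MK-2206 and tau and 21 in its interaction, and the opposite overlaps were 111 with tau and 28 for genotype without and MK-2206 with tau.

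Leaving out each library gave 1295 to 2975, 2640 to 4188, 2686 to 3373, 629 to 1041, 138 to 198, 150 to 245 and 2709 to 2913 genes for the pairwise comparisons, and 471 to 1537 and 9 to 43 for the interactions. Lists ranged over 11 to 14, 8 to 10, 12 to 15, 12 to 14, 9 to 13, 5 to 6 and 10 to 10, and 10 to 13 and 5 to 9. The shared tau response ranged from 1679 to 2480, the opposite overlaps from 74 to 144 with tau, 80 to 200 without, 52 to 115 and 20 to 71, and the MK-2206 overlap from 47 to 69. Trem2 for genotype without tau ranged from -1.61 to -1.04. On simulated data 43.3% of genes changed 2-fold were recovered, so true changes of that size may be missed.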

Other observations

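Treml2, a receptor gene beside Trem2 on chromosome 17, moved against Trem2 between the genotypes without tau, while of the 8 Trem2 neighbours tested 1 rose and 2 fell there (list median -0.61, not called, camera adjusted p = 0.504). It measured 5.63 ± 0.399 CPM in Trem2+/+ cells without tau (SD, n = 3), and rose from there to R47H/+ cells by a log2 change of 2.82 (SE 0.105). Tau raised Treml2 by 2.85 in Trem2+/+ cells, by 1.30 in R47H/+ cells and by 1.14 in R47H/+ cells with MK-2206. Its tau response was smaller in R47H/+ than in Trem2+/+ cells, with an interaction of -1.55 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 6.54e-06). With MK-2206 Treml2 was at -0.09 in cells with tau and was not called.

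Homeostatic microglia genes went different ways with tau. P2ry13 rose by 2.09 in Trem2+/+ cells, by 1.35 in R47H/+ cells and by 1.95 in R47H/+ cells with MK-2206, while Gpr34 fell by 3.32 in R47H/+ cells. Malat1 and Xist, long non-coding RNAs, were low in both length-shifted libraries, with 82.5 and 128.6 CPM in Trem2+/+ replicate 3 and 135.5 and 124.6 CPM in R47H/+ with tau replicate 2. Malat1 was chosen after its values were seen.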
